A study of Mus musculus with 10 samples.

How the data were processed

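RNA was sequenced from CD8+ T cells sorted from the spleens of 4 mice, and 10 libraries were analysed: 3 of the sort called TMEM, 3 of TINT and 4 of TEFF. One further TMEM sample and one further TINT sample had been left out by the submitters for low RNA quality, per the design text, and are not analysed here. Per the labels' protocols, RNA was extracted with a Zymo Research micro-scale kit and sent to BGI Genomics for library preparation and Illumina HiSeq sequencing. The labels name the molecule as total RNA. Whether the libraries were poly(A)-selected and whether they kept strand is not given in the sources used here, so reads of a gene and of an overlapping or antisense gene cannot be told apart.

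The authors deposited a table of normalised counts for 46517 gene symbols, per the file header, which was read as a signal that is never negative and is comparable across the 10 columns. The submitters' processing notes name Trimmomatic 0.32, Bowtie2 2.3.2, RSEM 1.2.31, DESeq2 and the mouse build mm10. The options of these tools, their order and the gene annotation are not given in the sources used here. How reads shared by near-identical gene copies were assigned is not given either, so values of histone genes, haemoglobin genes (Hba-a1 and Hba-a2), the Klra and Klrc families, metallothioneins, tubulins, Pira2 and Pilrb1 are uncertain between copies.

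Normalised counts summed to between 19340584 and 22566739 per library. In each library the low values lay on a ladder, but only 63.5 to 66.3% of values of up to 20 steps were whole multiples of the step within 0.001 step. Whole reads were therefore not recovered, no count model was applied here and no counting intervals are given. The step, which stands for about 1 read, was 0.945 to 1.052 normalised counts. The error given with each mean is the spread between libraries.

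Genes with at least 10 normalised counts in at least 3 of the 10 libraries were kept, which left 15332 genes and set aside 31185. Values were tested as log2(value + 1) with limma 3.58.1 in R 4.3.3. All 10 libraries entered one fit with a mean per sort, 7 residual degrees of freedom, empirical Bayes with a mean-variance trend, and no other term. A fold change is on the log2(value + 1) scale, which understates the change of low genes. Benjamini-Hochberg adjustment was made within each comparison, and a gene was called at an adjusted p under 0.05. The comparisons were TMEM with TEFF, TINT with TEFF, TINT with TMEM, and TINT with the midpoint of TMEM and TEFF. The samples, tests, gene lists, rule for named genes and changes of processing to be tried were fixed before the data were examined. For the sort markers, a two-sided exact permutation test of the group means was added, whose smallest possible p is 0.0571 for 3 against 4 libraries and 0.1 for 3 against 3.

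The position of TINT between the other sorts was computed on the genes called in a fit of the TMEM and TEFF libraries alone. Each TINT library was projected on that axis, with 0 at the TEFF mean and 1 at the TMEM mean. For overlaps of calls between comparisons that share libraries, 100 simulations of unchanged groups gave the overlap with no effect, and the product of the list sizes over the genes tested gave that of independent lists.

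The 26 gene lists held 367 genes, 1 of which (Ahsp) was not found in the table. Cd244a was matched under its older symbol Cd244. The lists were stem and memory genes, cytotoxic effector molecules, terminal effector regulators and trafficking, S phase genes, G2/M phase genes, inhibitory receptors and exhaustion regulators, chemokine receptors and adhesion, NK-type receptors, type I interferon response, immediate early genes, heat shock genes, tissue residency genes, cytokine receptors, glycolysis enzymes, oxidative phosphorylation and cholesterol synthesis. Markers of other cells were those of B cells, plasma cells, antigen-presenting myeloid cells, neutrophils, erythroid cells, platelets, CD4 and regulatory T cells, NK cells and gamma delta T cells, and T cell identity genes formed the last list. Each list was tested with limma camera at a preset correlation of 0.01, with adjustment over the 26 lists of a comparison. Camera with an estimated correlation and fry, which asks whether a list's genes move one way on balance and compares it with no other genes, were run beside it. With the estimated correlation, calls held for 2 lists in TINT against TMEM and for 0 in each other comparison, although 12, 13, 14 and 10 lists passed in the 4 comparisons at the preset value. By fry 20, 15, 8 and 4 lists passed.

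Named genes were chosen by rule. Cxcr3, Klrg1, Tcf7, Mki67 and Gzmb were always named. To them were added the 6 largest rises and 6 largest falls among called genes with a mean of at least 50 in the higher group and no overlap between the groups' libraries, without predicted gene models, pseudogenes and receptor or immunoglobulin segments. The last part took up to 4 members of smallest p from each list that passed. For the midpoint comparison the other group was taken as the 7 remaining libraries together, a reading made when the rule was applied. One gene that the rule names is not reported here. AC107830.1, a clone-named gene that the wording of the rule let through, is included. Coordinates are those of GENCODE M21 on GRCm38 (mm10), joined by symbol for 14250 of the 15332 genes tested (92.9%).

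Sample titles carry the numbers 1 to 4 in each sort, and the design text says that the sorts came from the same 4 mice, so a number was taken to mark a mouse. This was checked on the deviations from the sort means before fits with and without the pairing were compared. Over 86 T cell receptor V segment genes, 8 same-number pairs of libraries correlated at 0.66 on average (0.54 to 0.76), and 25 different-number pairs at -0.21 (-0.65 to 0.31). All 10 libraries had their best partner under their own number. Over all 15332 genes the averages were 0.11 (-0.04 to 0.29) and -0.04 (-0.24 to 0.21). TMEM and TINT share only the numbers 1 and 4. A fit with the number as a block was also made, and its values are given where it changed a call or moved a count by over 1.5 times.

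The pipeline was tested on simulated data with the real means and 100 genes changed at each of 2 sizes among 15332. In TMEM against TEFF it recovered 40% of 2-fold and 67% of 4-fold changes, and 13 of 120 calls (10.8%) were false. In TINT against TEFF it recovered 45% and 74% with 4.8% false calls, and in TINT against TMEM 41% and 71% with 3.45%. A simulated position of 0.7 came back as 0.69.

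The fits were repeated with changes to the pseudocount, the filter, the scaling, the libraries in the fit, the variance prior, the sample weights, the block, the receptor segment genes and each library in turn. A further 3 were added after the values were seen: leaving out TMEM 1, TMEM 2 and TINT 4, which had the highest level of markers of other cells, and using either that level or the ribosomal RNA level as a covariate. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.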

Results

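Gene expression was measured in spleen CD8+ T cells of mice infected for 6 weeks with Toxoplasma gondii, a protozoan parasite that persists in its host. The mice were F1 offspring of C57BL/6 and B6.C-H2d parents. Cells that bound a tetramer for the parasite antigen GRA6 and carried neither B220 nor CD4 were sorted by the chemokine receptor CXCR3 and by KLRG1, a receptor of differentiated effector cells. TMEM cells were CXCR3+ KLRG1- (n = 3), TINT cells CXCR3+ KLRG1+ (n = 3) and TEFF cells CXCR3- KLRG1+ (n = 4). The series title places the data within a question about CXCR3 and stem-like and proliferating CD8+ T cells in chronic infection. Normalised counts summed to between 19340584 and 22566739 per library, and 13809 to 14990 genes per library reached 10.

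Transcripts of both sort markers followed the labels. Cxcr3 (X:101731535-101734269, minus strand) averaged 12680 ± 2140 normalised counts in TMEM (SD, n = 3), 7220 ± 1180 in TINT (n = 3) and 1180 ± 279 in TEFF (n = 4). It was 10.9-fold higher in TMEM than in TEFF (limma adjusted p = 2.4e-06) and 6.2-fold higher in TINT than in TEFF (adjusted p = 1.01e-05). Klrg1 (6:122270596-122282882, minus strand) averaged 864.5 ± 265 in TMEM, 14810 ± 1700 in TINT and 23490 ± 2300 in TEFF. It was 17.5-fold higher in TINT than in TMEM (adjusted p = 1.22e-06), and its log2 fold change was -4.80 ± 0.18 (SE) in TMEM against TEFF (adjusted p = 1.02e-07). For both genes every TMEM and TINT library was separate from every TEFF library, and the exact two-sided permutation p was 0.0571, the smallest that 3 against 4 libraries can give. Because cells were sorted on both proteins, these values check the labels and are no finding. Cd8a averaged 24850 ± 2210, 21010 ± 1810 and 23900 ± 2820, with adjusted p of 0.312 to 0.765 across the comparisons. Cd4 was low but higher in TMEM (123.6 ± 90.8) than in TEFF (4.403 ± 5.03; log2 fold change 4.91 ± 0.88, adjusted p = 0.00179).

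**Figure D1:**
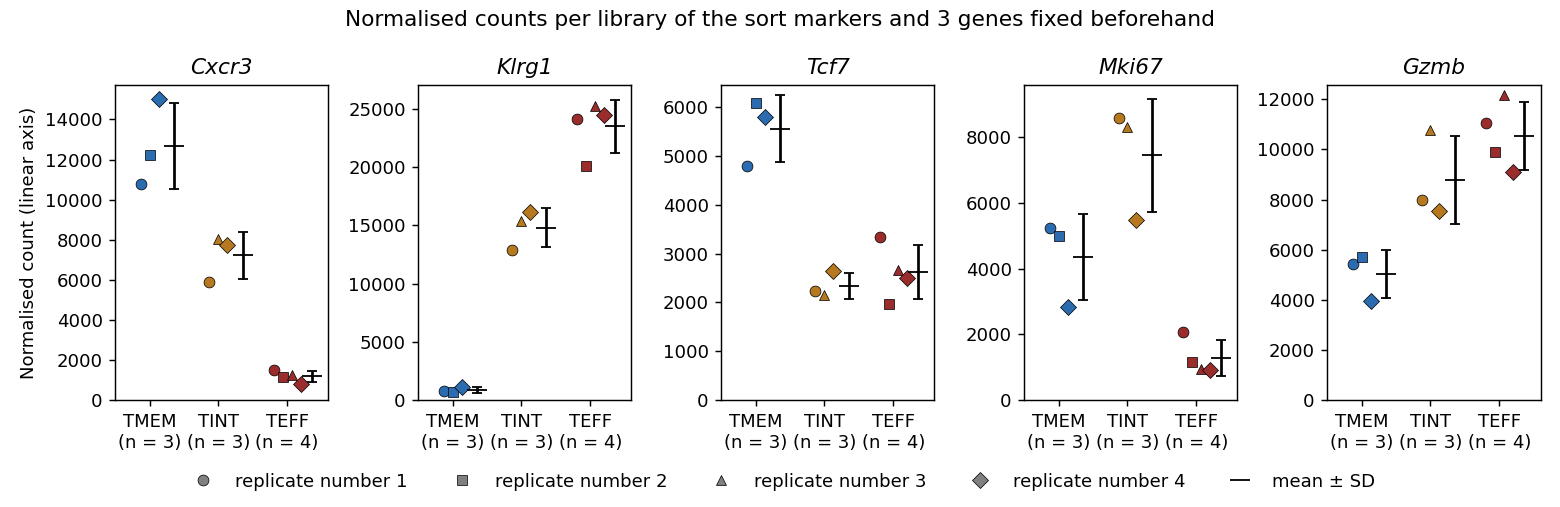
Normalised counts (linear axis) of selected genes in each library, grouped by sort (TMEM n = 3, TINT n = 3, TEFF n = 4). Points are libraries, and dashes with error bars are group means ± SD. Cxcr3 falls from 12680 in TMEM to 1180 in TEFF, and Klrg1 is lowest in TMEM at 864.5.

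The largest axis of variation, with 44.1% of the variance, separated the 4 TEFF libraries from the 6 others. Markers of other cells also differed between libraries. Antigen-presenting myeloid cell markers took 37.5 ± 23.5 per 10000 normalised counts in TMEM, 26.1 ± 22 in TINT and 4.42 ± 0.838 in TEFF (SD). TMEM 1, TMEM 2 and TINT 4 held 55.4, 46.18 and 50.75 per 10000, against 8.54 to 19 in the other TMEM and TINT libraries. TMEM 1 and TMEM 2 carried Siglech, a plasmacytoid dendritic cell gene, at 4335 and 2193, against 5 to 109 elsewhere. TINT 4 carried the macrophage genes C1qb and Csf1r at 7183 and 9372. Ribosomal RNA genes (18S and mitochondrial) took 1.33 ± 0.574% of counts in TMEM, 1.72 ± 0.0819% in TINT and 0.345 ± 0.187% in TEFF.

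**Figure D2:**
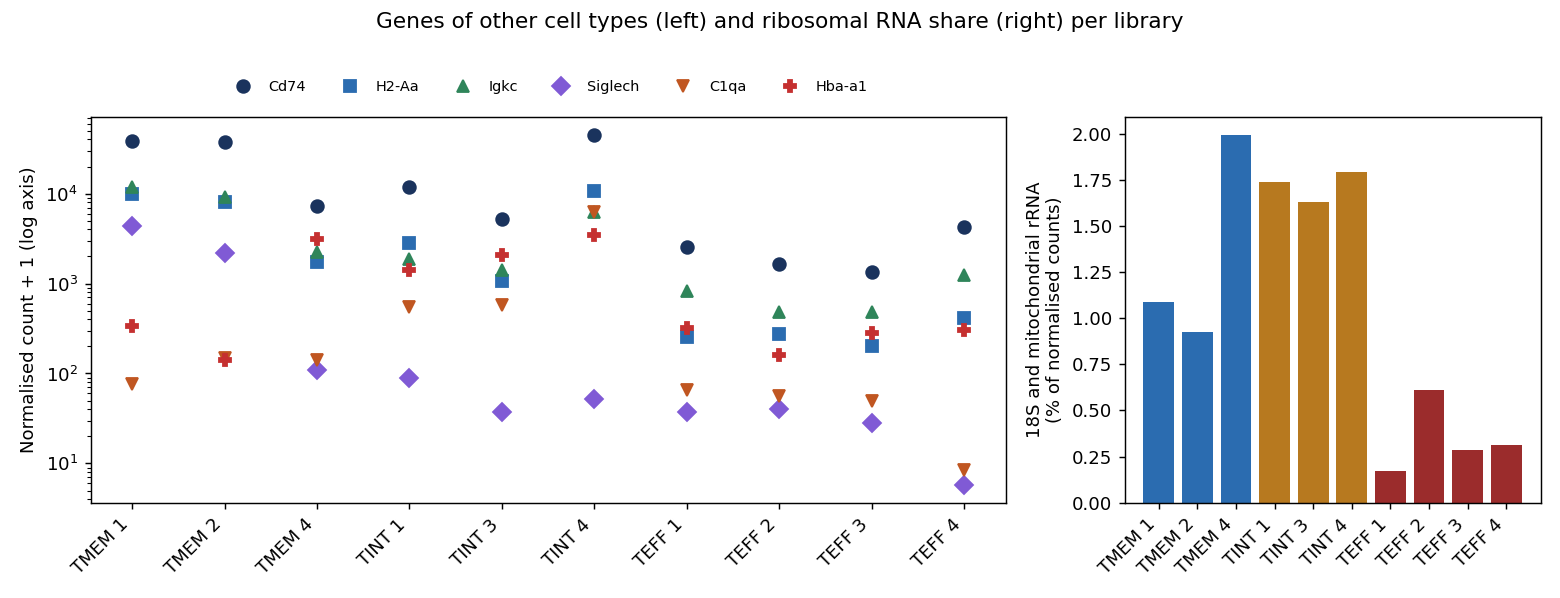
Levels per library of markers of other cell types and of ribosomal RNA, with 1 point per library and libraries grouped by sort. Siglech was highest in TMEM 1 and TMEM 2 (4335 and 2193) and C1qa in TINT 4 (6223), and ribosomal RNA took 0.171 to 0.61% in TEFF libraries.

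TMEM cells carried more transcripts of stem and memory genes and of cell division genes than TEFF cells, and fewer of terminal effector regulators and NK-type receptors. These list calls rest on a preset correlation between genes, and none held with an estimated one (adjusted p 0.0773 to 0.252). By fry, which compares a list with no other genes, all of these lists passed (adjusted p 1.48e-05 to 0.000776). Tcf7 (11:52252371-52283014), which encodes TCF-1, a transcription factor of stem-like T cells, averaged 5555 ± 681 in TMEM (SD, n = 3) and 2618 ± 559 in TEFF (n = 4), a log2 fold change of 1.10 ± 0.17 (SE; adjusted p = 0.00067). Mki67 (7:135689784-135716361), a gene of dividing cells, averaged 4357 ± 1320 and 1274 ± 543 (1.81 ± 0.30; adjusted p = 0.00113). Gzmb (14:56258838-56262260), encoding the cytotoxic protease granzyme B, averaged 5031 ± 946 in TMEM and 10550 ± 1350 in TEFF (-1.08 ± 0.17; adjusted p = 0.000825). Of 15332 genes, 2385 were higher and 1871 lower in TMEM, and 1428 and 595 of them by over 2-fold. Libraries of the sorts did not overlap for 36% of genes, where chance gives 5.71%.

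Of 20 stem and memory genes, 15 were higher in TMEM than in TEFF and 0 lower (16 and 0 adjusted over the list alone, camera adjusted p = 4.67e-09). With an estimated correlation the adjusted p = 0.0773. Socs3 (11:117966079-117970047), a feedback inhibitor of cytokine signalling, had the largest rise of the named genes in TMEM against TEFF, from 13.21 ± 6.88 in TEFF to 829.2 ± 322 in TMEM (log2 fold change 6.02 ± 0.49). Ccr7, a receptor for homing to lymphoid tissue, averaged 2176 ± 850 against 61.9 ± 21.5 (5.11 ± 0.46), Id3, an inhibitor of E-protein transcription factors, 661.7 ± 453 against 23.42 ± 7.06 (4.59 ± 0.47), and Slamf6 3313 ± 757 against 310.5 ± 130 (3.48 ± 0.28). Terminal effector regulators and trafficking genes were lower for 10 of 14 and higher for 0 (11 lower adjusted over the list alone, camera adjusted p = 9.72e-08). With an estimated correlation the adjusted p = 0.25. They included S1pr5, a receptor for egress from tissue (-2.85 ± 0.26), Cx3cr1 (-2.13 ± 0.20), Bhlhe40 (-1.53 ± 0.14) and Klf3 (-1.30 ± 0.12). NK-type receptors were lower for 8 of 13 (9 adjusted over the list alone, camera adjusted p = 1.11e-05, and adjusted p = 0.0918 with an estimated correlation). Klrg1, on which cells were sorted, was one of them, beside Klrb1c (-3.83 ± 0.18), Klra9 (-3.92 ± 0.40) and Klrc1 (-2.16 ± 0.21).

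Cell division genes were the lists with the smallest p. Of 28 S phase genes 26 were higher in TMEM (26 adjusted over the list alone, median log2 fold change 1.71, camera adjusted p = 1.14e-14, and adjusted p = 0.252 with an estimated correlation). Among them were Uhrf1 (2.57 ± 0.23), E2f8 (2.86 ± 0.28), Dtl (2.37 ± 0.24) and the replicative helicase gene Mcm5 (1.97 ± 0.20). All 28 G2/M genes were higher by both adjustments, over all genes and adjusted over the list alone (median 2.29, camera adjusted p = 9.59e-18, and adjusted p = 0.252 with an estimated correlation). Ccna2, encoding cyclin A2, averaged 4293 ± 1460 against 608.8 ± 165 (2.79 ± 0.25). Log2 fold changes were 3.40 ± 0.34 for Cenpf, 2.71 ± 0.25 for Hmmr and 2.71 ± 0.26 for Aurkb. Among inhibitory receptors and exhaustion regulators 10 of 14 were higher and 1 lower (10 and 1 adjusted over the list alone, camera adjusted p = 0.000107, and adjusted p = 0.252 with an estimated correlation). Ctla4 (4.34 ± 0.64), Cd200 (3.55 ± 0.47), Tigit (1.76 ± 0.20) and Cd160 (1.73 ± 0.12) led that group. These were also sorts with unequal ribosomal RNA, at 1.33% in TMEM and 0.345% in TEFF.

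Smaller groups moved as well. Of 18 type I interferon response genes 8 were higher and 2 lower (10 and 2 adjusted over the list alone, camera adjusted p = 0.0259, and adjusted p = 0.376 with an estimated correlation). Members included Oas3 at 1.26 ± 0.19, Oas1a at 1.17 ± 0.19 and Usp18 at 1.17 ± 0.17, while Ifit2 was lower at -0.78 ± 0.14. Immediate early genes were higher for 8 of 17 and lower for 2 (8 and 2 adjusted over the list alone, camera adjusted p = 0.0497, and adjusted p = 0.252 with an estimated correlation). Members included Jun at 2.38 ± 0.20, Cd69 at 0.97 ± 0.21, Atf3 at 3.13 ± 0.70 and Egr1 at 1.89 ± 0.48. Glycolysis enzymes were higher for 7 of 14 (7 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.0149, and adjusted p = 0.461 with an estimated correlation). Members included Gapdh at 1.40 ± 0.15, Tpi1 at 1.19 ± 0.14, Pgam1 at 0.87 ± 0.11 and Gpi1 at 0.79 ± 0.12. Cholesterol synthesis genes were higher for 9 of 15 and lower for 2 (9 and 2 adjusted over the list alone, camera adjusted p = 0.018, and adjusted p = 0.476 with an estimated correlation). Srebf2 (1.23 ± 0.21) and Mvk (1.09 ± 0.22) were higher and Dhcr7 (-0.88 ± 0.13) was lower. Without TEFF 2 the interferon list had an adjusted p of 0.0502, and without TMEM 2 the cholesterol list had 0.0539 and Egr1 0.0583. The immediate early list lost its call without TMEM 2 (0.068), TINT 3 (0.0514), TINT 4 (0.0536) or TEFF 2 (0.0603). Genes higher fell without TMEM 1 or TMEM 2 to 4 and 5 for the interferon list and 5 and 3 for the immediate early list, and without TMEM 2 to 4 for the cholesterol list.

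Markers of other cells differed between the same sorts. Antigen-presenting myeloid cell markers were higher in TMEM for 11 of 16 (13 adjusted over the list alone, camera adjusted p = 1.39e-05, and adjusted p = 0.34 with an estimated correlation). Members included the MHC class II gene H2-Aa at 6615 ± 4310 against 284 ± 89.8 (4.24 ± 0.71), H2-Eb1 at 3.95 ± 0.73, Flt3 at 4.72 ± 0.85 and Mpeg1 at 4.38 ± 0.80. B cell markers were higher for 4 of 12 (4 adjusted over the list alone and 9 of 12 with the replicate block, camera adjusted p = 0.00263, and adjusted p = 0.461 with an estimated correlation). Members included Cd22 at 2.73 ± 0.38, Ighm at 3.56 ± 0.65, Igkc at 3.17 ± 0.60 and Cd79b at 2.71 ± 0.80. Cd79b lost its call without any one of TMEM 1, 2 or 4 (adjusted p 0.0539 to 0.0788) or TEFF 1, 2 or 3 (0.0509 to 0.0602), and without TEFF 4 there were 9 B cell markers higher. The remaining largest rises included Wdfy4 (5.70 ± 1.06), a gene of cross-presenting dendritic cells, Apol7c (5.80 ± 0.97), Cdh1 (6.01 ± 0.71) and Klk1 (5.65 ± 1.03). Klk1 was at 4.598 without TMEM 1 and 7.156 without TMEM 4. Without TMEM 1, TMEM 2 and TINT 4, Klk1 was at 2.65, Wdfy4 at 4.318, Apol7c at 4.879, Flt3 at 2.603 and Mpeg1 at 2.149. Of the B cell genes, Cd22 was then at 2.189, Ighm at 2.459 and Igkc at 1.698, while Cd79b was at 2.893. That fit leaves 1 TMEM library, so no call is read from it here. Pakap was listed at 0 in every TEFF library and averaged 58.91 ± 11 in TMEM. The largest falls besides Klrg1 were Cdhr1 (-5.75 ± 0.39), AC107830.1 (-5.62 ± 1.22), Tsks (-4.95 ± 0.51), Srcin1 (-4.93 ± 0.65) and Plin5 (-4.61 ± 0.61).

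Other lists did not pass in TMEM against TEFF at the preset correlation. Cytotoxic effector molecules were higher for 3 of 17 and lower for 7 (5 and 7 adjusted over the list alone; adjusted p = 0.054, and 0.0309 with the replicate block). CD4 and regulatory T cell markers had an adjusted p of 0.0554 (0.0309 with the block) and NK cell markers 0.078 (0.0309 with the block). Adjusted p was 0.941 for chemokine receptors and adhesion, 0.139 for heat shock genes, 0.0746 for tissue residency genes, 0.16 for cytokine receptors, 0.264 for oxidative phosphorylation, 0.177 for plasma cell markers, 0.264 for neutrophil markers, 0.416 for erythroid markers, 0.941 for platelet markers, 0.772 for gamma delta T cell markers and 0.0746 for T cell identity genes. After quantile normalisation, adjusted over 28 lists with the histone and ribosomal protein sets added, tissue residency genes (0.0714 to 0.0336) and CD4 and regulatory T cell markers (0.0522 to 0.0336) came under 0.05.

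The number of calls depended on the libraries and the scaling. Without TMEM 1, TMEM 2 and TINT 4, which leaves TMEM 4 as the only TMEM library, Mki67 had a log2 fold change of 1.24 in TMEM against TEFF. A single library gives no spread for its sort, so no call in TMEM against TEFF is read from that fit. With the level of markers of other cells as a covariate 107 genes were higher and 75 lower in TMEM than in TEFF, and with the ribosomal RNA level 827 and 451. Quantile normalisation, which moved the median fold change of all genes to -0.096, turned the split to 2128 higher and 2553 lower, or 45.5% higher in place of 56%. Without TMEM 1 the number of genes lower was 1190, and without TMEM 2 it was 1209.

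**Figure D3:**
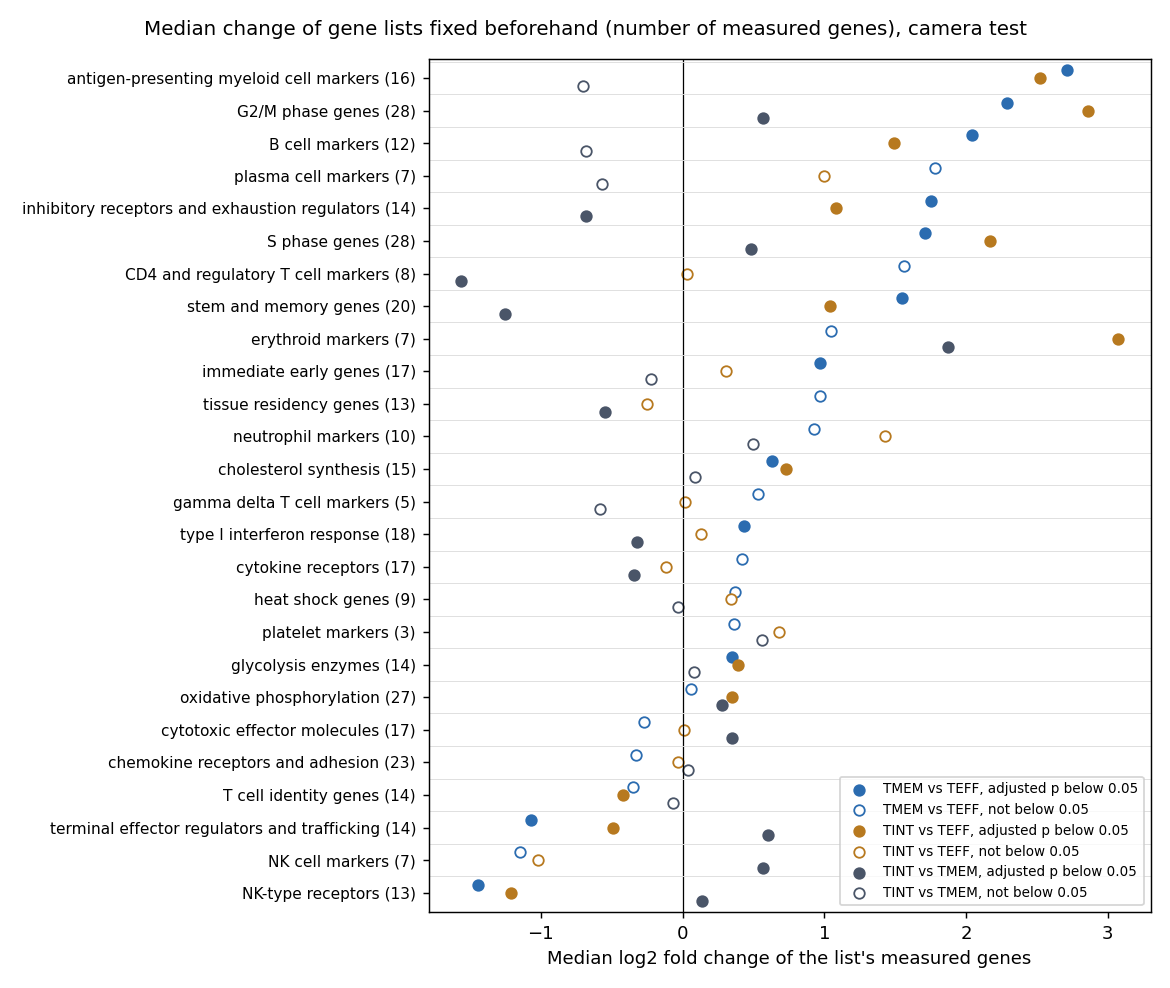
Median log2 fold change of each gene list (x axis) in the comparisons between sorts, with markers for lists whose camera adjusted p passed the threshold. G2/M and S phase genes have medians of 2.29 and 1.71 in TMEM against TEFF, and terminal effector regulators have -1.07.

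TINT cells, which carry both sort markers, had more transcripts of cell division genes than TEFF cells, and fewer of NK-type receptors and terminal effector regulators. None of these list calls held with an estimated correlation (adjusted p 0.292 to 0.43). By fry these lists passed (adjusted p 0.000254 to 0.00896), while B cell markers, called by camera in this comparison, did not (0.156). Mki67 averaged 7458 ± 1720 in TINT (SD, n = 3) against 1274 ± 543 in TEFF (n = 4), a log2 fold change of 2.6 ± 0.30 (SE; adjusted p = 0.000103). All 28 G2/M genes were higher (28 adjusted over the list alone, median 2.86, camera adjusted p = 3.35e-22, and adjusted p = 0.43 with an estimated correlation), with Ccna2 (3:36564865-36572150) at 7333 ± 896 against 608.8 ± 165 (3.62 ± 0.25), Cdca3 at 3.39 ± 0.27, Hmmr at 3.27 ± 0.25 and Aurkb at 3.23 ± 0.26. Of 28 S phase genes 27 were higher (27 adjusted over the list alone, median 2.17, camera adjusted p = 8.82e-20, and adjusted p = 0.43 with an estimated correlation), with E2f8 at 3.53 ± 0.28, Clspn at 3.50 ± 0.28, Uhrf1 at 3.05 ± 0.23 and Gmnn at 2.62 ± 0.20. In all, 2417 genes were higher and 1936 lower in TINT than in TEFF, 1296 and 607 by over 2-fold, and libraries did not overlap for 34.9% of genes (5.71% by chance).

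Stem and memory genes were higher in TINT for 10 of 20 and lower for 2 (10 and 3 adjusted over the list alone, camera adjusted p = 0.0159, and adjusted p = 0.43 with an estimated correlation). Eomes, a T-box transcription factor, averaged 794.5 ± 148 against 149.7 ± 31 (2.41 ± 0.25), Slamf6 1379 ± 284 against 310.5 ± 130 (2.22 ± 0.28), Myb 73.1 ± 16.2 against 6.048 ± 4.48 (3.58 ± 0.48) and Socs3 135.3 ± 23.8 against 13.21 ± 6.88 (3.47 ± 0.49). Tcf7 was not separated from TEFF, at 2336 ± 261 against 2618 ± 559 (-0.14 ± 0.17; adjusted p = 0.553), and neither was Gzmb, at 8762 ± 1750 against 10550 ± 1350 (-0.28 ± 0.17; adjusted p = 0.248). Klrg1 was lower in TINT than in TEFF (-0.67 ± 0.18; adjusted p = 0.0159, and 0.0614 without TINT 1). Terminal effector regulators and trafficking genes were lower for 6 of 14 (8 adjusted over the list alone and 10 after quantile normalisation, camera adjusted p = 0.00383, and adjusted p = 0.43 with an estimated correlation), among them S1pr5 (-1.35 ± 0.26), Prdm1 (-1.06 ± 0.22), Bhlhe40 (-0.73 ± 0.14) and Klf3 (-0.72 ± 0.12). NK-type receptors were lower for 9 of 13 (9 adjusted over the list alone, camera adjusted p = 0.000147, and adjusted p = 0.292 with an estimated correlation). Klrb1c averaged 258.6 ± 42.5 in TINT and 2484 ± 422 in TEFF (-3.25 ± 0.18), and Klra9, Klrc1 and Klrc2 had log2 fold changes of -2.99 ± 0.40, -1.66 ± 0.21 and -1.21 ± 0.17.

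Metabolic lists were higher in TINT than in TEFF. Glycolysis enzymes were higher for 7 of 14 and lower for 1 (8 and 1 adjusted over the list alone, camera adjusted p = 0.00277, and adjusted p = 0.43 with an estimated correlation). Members included Gapdh at 1.75 ± 0.15, Tpi1 at 1.45 ± 0.13, Ldha at 0.98 ± 0.14 and Pgam1 at 0.90 ± 0.11. Oxidative phosphorylation genes were higher for 12 of 27 (14 adjusted over the list alone, camera adjusted p = 0.000318, and adjusted p = 0.582 with an estimated correlation). Members included Atp5b at 0.98 ± 0.13, Ndufa4 at 0.81 ± 0.14, Cox5a at 0.70 ± 0.13 and Cox4i1 at 0.59 ± 0.11. Cholesterol synthesis genes were higher for 9 of 15 (11 adjusted over the list alone, camera adjusted p = 0.00135, and adjusted p = 0.43 with an estimated correlation). Members included Idi1 at 1.21 ± 0.22, Fdps at 0.99 ± 0.19 and Srebf2 at 0.98 ± 0.21. Inhibitory receptors and exhaustion regulators were higher for 6 of 14 (9 higher and 1 lower adjusted over the list alone and 10 higher with the replicate block, camera adjusted p = 0.00528, and adjusted p = 0.43 with an estimated correlation). Members included Ctla4 at 2.85 ± 0.64, Tox2 at 1.92 ± 0.52, Tigit at 1.65 ± 0.20 and Cd160 at 1.10 ± 0.12. Tox2 lost its call without TINT 4 (adjusted p = 0.0551). Ribosomal RNA took 1.72% of counts in TINT and 0.345% in TEFF, so it moved with these lists.

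Markers of other cells were higher in TINT than in TEFF for several types. Antigen-presenting myeloid cell markers were higher for 10 of 16 (12 adjusted over the list alone, camera adjusted p = 0.00021, and adjusted p = 0.43 with an estimated correlation). Members included Itgax at 1.91 ± 0.21, Csf1r at 4.54 ± 0.77, Adgre1 at 4.25 ± 0.78 and Cd14 at 3.92 ± 0.72. Itgax varied less within sorts (log2 SD 0.32) than the list did (median 1.2). It was at 3229, 3798 and 4006 in TINT 1, TINT 3 and TINT 4, and at 1952, 1581 and 2628 in TMEM 1, TMEM 2 and TMEM 4. Itgax therefore did not follow the libraries rich in the other markers, and its source was not tested. Erythroid markers were higher for 3 of 7 (5 adjusted over the list alone, camera adjusted p = 0.0219, and adjusted p = 0.43 with an estimated correlation). Members included Hbb-bs at 1439 ± 598 against 120.3 ± 39.8 (3.55 ± 0.67) and Hba-a1 and Hba-a2 at 3.07 ± 0.78 and 3.13 ± 0.80, while Alas2 was at 1.89 ± 0.66 (adjusted p = 0.0526). B cell markers were higher for 2 of 12 (1 adjusted over the list alone and 4 with the replicate block, camera adjusted p = 0.0267, and adjusted p = 0.69 with an estimated correlation). Cd22 (1.5 ± 0.38) and Igkc (1.87 ± 0.60; adjusted p = 0.0375, 0.0554 with the block) were called, and Blk (2.03 ± 0.77; adjusted p = 0.0686, 0.0173 with the block) and Ighm (1.59 ± 0.65; adjusted p = 0.0911) were not. T cell identity genes were lower for 7 of 14 (2 higher and 8 lower adjusted over the list alone, camera adjusted p = 0.0267, and adjusted p = 0.582 with an estimated correlation). Members included Cd3e, a subunit of the T cell receptor complex, at 6548 ± 412 against 19540 ± 2190 (-1.57 ± 0.13), Thy1 at -0.72 ± 0.19, Lck at -0.69 ± 0.14 and Cd8b1 at -0.69 ± 0.18.

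Single libraries decided several of these marker calls. T cell identity genes lower fell to 3 without TINT 1 or TINT 3 and to 4 without TINT 4. Erythroid genes higher were 1 without TINT 4 and 5 without TMEM 2, and B cell genes higher were 0 without TINT 4 and 5 without TEFF 4. Without TINT 4 the adjusted p was 0.0569 for Cd22, 0.162 for Igkc, 0.0531 for Hba-a1, 0.0511 for Hba-a2 and 0.0501 for Thy1. Igkc also lost its call without TINT 1 (0.053), TEFF 1 (0.0549), TEFF 2 (0.0793) or TEFF 3 (0.0904), and Cd8b1 without TINT 1 (0.0541) or TINT 3 (0.0823), while Blk was called without TEFF 4 (0.0183) and Ighm without TINT 3 (0.0338) or TEFF 4 (0.046). Alas2 was called without TMEM 2 (0.0309) or TINT 1 (0.0281). The B cell list lost its call without TINT 4 (0.268), TEFF 1 (0.0605), TEFF 2 (0.0945) or TEFF 3 (0.0593), the erythroid list without TEFF 2 (0.0587), and the T cell identity list without TINT 1 (0.0839) or TEFF 3 (0.0532). Neutrophil markers had an adjusted p of 0.133 (0.0101 with the block). The largest rises besides these were Hist1h2an, listed at 0 in every TEFF library and at 94.71 ± 8.44 in TINT, Pilrb1 (5.98 ± 0.83), Pira2 (5.77 ± 0.93), the macrophage genes Cd5l (5.64 ± 0.80) and Mertk (5.56 ± 0.90), and Hist2h3c2 (5.36 ± 0.95). Without TINT 4, Pilrb1 was at 4.869, Pira2 at 4.468, Cd5l at 4.584 and Mertk at 4.285, and Cd5l was at 334.7, 198.3 and 2305 in TINT 1, TINT 3 and TINT 4. The largest falls besides Klrb1c and Klra9 were AC107830.1 (-6.69 ± 1.22), Cdhr1 (-3.76 ± 0.39), Srcin1 (-2.93 ± 0.65) and Zcchc14 (-2.86 ± 0.64). Without TMEM 1, TMEM 2 and TINT 4, 1504 genes were higher and 1158 lower in TINT than in TEFF, including 28 G2/M, 26 S phase, 7 stem and memory and 9 antigen-presenting myeloid cell genes among those higher, and the B cell list lost its call (0.229). With the level of markers of other cells as a covariate 532 genes were higher and 239 lower, and with the ribosomal RNA level 688 and 267. Quantile normalisation, which moved the median of all genes to -0.106, gave 2109 higher and 2573 lower, or 45% higher in place of 55.5%, and without TINT 3 the number lower was 1250.

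Fewer genes separated TINT from TMEM than separated either from TEFF. TINT cells had fewer stem and memory transcripts than TMEM cells and more of effector genes. With an estimated correlation the stem and memory list kept its call (adjusted p = 0.0248) and the effector lists lost theirs (0.127). By fry these lists passed (adjusted p 0.000882 to 0.0134). Tcf7 averaged 2336 ± 261 in TINT (SD, n = 3) and 5555 ± 681 in TMEM (n = 3), a log2 fold change of -1.25 ± 0.18 (SE; adjusted p = 0.014, and 0.0504 with the replicate block). In all, 76 genes were higher and 90 lower in TINT by limma, 49 and 64 by over 2-fold, while 2201 had an unadjusted p under 0.05 and libraries did not overlap for 20.9% of genes (10% by chance). With the replicate block 35 were higher and 26 lower, and 50 of these 61 were also called without it. Higher and lower were 7 and 2 without TMEM 2, 14 and 10 without TINT 3, 23 and 19 without TMEM 1, 33 and 25 without TINT 1, 13 and 33 without TINT 4, and 37 and 42 without TEFF 3. Array weights gave 365 and 408. Mki67 (0.80 ± 0.32; adjusted p = 0.279), Gzmb (0.80 ± 0.18; adjusted p = 0.0623) and Cxcr3 (-0.81 ± 0.21; adjusted p = 0.0964) did not pass.

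Stem and memory genes were lower in TINT than in TMEM for 6 of 20 (1 higher and 17 lower adjusted over the list alone, and 2 lower with the replicate block). The list's median was -1.25 and its call held with an estimated correlation (camera adjusted p = 7.4e-13, and adjusted p = 0.0248 with an estimated correlation). Besides Tcf7 they included the survival gene Bcl2 (-1.42 ± 0.23; adjusted p = 0.0201), the interleukin-7 receptor gene Il7r (-1.26 ± 0.22; adjusted p = 0.0231, and 0.0547 with the block) and Ccr7 (-2.52 ± 0.49; adjusted p = 0.0366). All of these lost their calls without TMEM 2 (adjusted p 0.0746 to 0.156) and without TINT 3 (0.0668 to 0.101). Bcl2 and Ccr7 also lost them without TMEM 1 (0.0578 and 0.0643), Il7r and Ccr7 without TINT 1 (0.071 and 0.0687), Bcl2 and Il7r without TINT 4 (0.0524 and 0.059), and Ccr7 without TMEM 4 (0.066) or TEFF 3 (0.0598). Bcl2 was not separated between TMEM and TEFF (2253 ± 161 and 2344 ± 542, limma adjusted p = 0.927). TINT, at 865 ± 276, was below both, so Bcl2 does not mark a shift from TMEM towards TEFF.

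Effector genes went the other way. Terminal effector regulators and trafficking genes were higher in TINT for 4 of 14 (8 adjusted over the list alone, and 1 with the replicate block, camera adjusted p = 4.8e-08, and adjusted p = 0.127 with an estimated correlation). Cx3cr1 (9:119901616-120069879), a receptor of circulating effector cells, averaged 12920 ± 1230 against 4112 ± 951 (1.67 ± 0.21; adjusted p = 0.00793), and kept its call in the block (0.0388) and without any single library. S1pr5 (1.5 ± 0.27), Klf2 (0.91 ± 0.19) and Bhlhe40 (0.80 ± 0.14) had adjusted p of 0.0289, 0.0453 and 0.0276, and 0.109, 0.0916 and 0.0892 with the block. Cytotoxic effector molecules were higher for 2 of 17 (5 adjusted over the list alone, and 1 with the block, camera adjusted p = 9.6e-05, and adjusted p = 0.127 with an estimated correlation). The granzyme genes Gzma (31690 ± 17300 against 7793 ± 2440; 1.92 ± 0.35; adjusted p = 0.0289) and Gzmk (6725 ± 1490 against 2979 ± 1020; 1.2 ± 0.23; adjusted p = 0.0317, and 0.0732 with the block) were called, and Serpinb9 (0.57 ± 0.15; adjusted p = 0.104) was not. Apart from Cx3cr1, these calls did not hold without TMEM 2 (adjusted p 0.0919 to 0.177), TINT 3 (0.0686 to 0.133) or TINT 4 (0.0603 to 0.089). Further losses were without TMEM 1 for all but S1pr5 (0.0807 to 0.123), without TINT 1 for Bhlhe40, S1pr5 and Klf2 (0.071 to 0.113), without TEFF 3 for all but Bhlhe40 (0.051 to 0.0667), and for Klf2 without TMEM 4 (0.0577) or TEFF 4 (0.0635). Gzmk was not separated between TMEM and TEFF (2979 ± 1020 and 3451 ± 399, limma adjusted p = 0.397). TINT was above both, so Gzmk does not mark a shift from TMEM towards TEFF either.

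Several lists passed in TINT against TMEM with few or no single genes called. By fry, S phase (adjusted p = 0.167), G2/M (0.215) and oxidative phosphorylation genes (0.134) did not pass. Nor did inhibitory receptors (0.134), erythroid markers (0.167) or NK cell markers (0.188). S phase genes (0 of 28 called over all genes and 3 adjusted over the list alone, median 0.48, camera adjusted p = 9.79e-08) and G2/M genes (0 of 28 by either adjustment, over all genes or adjusted over the list alone, median 0.57, camera adjusted p = 9.79e-08) were higher, with adjusted p = 0.405 and 0.412 with an estimated correlation. Pcna (0.63 ± 0.16), Tipin (0.59 ± 0.16), Ccna2 (0.83 ± 0.27) and Cdk1 (0.86 ± 0.29) had adjusted p of 0.0848 to 0.189. Oxidative phosphorylation genes had a median of 0.28 (0 of 27 called, and 0 adjusted over the list alone, camera adjusted p = 3.14e-06, and adjusted p = 0.405 with an estimated correlation). CD4 and regulatory T cell markers were lower for 1 of 8 (3 adjusted over the list alone, camera adjusted p = 0.000137, and adjusted p = 0.0482 with an estimated correlation). Tnfrsf4 was the member called (43.51 ± 10.1 against 133.8 ± 13.1; -1.62 ± 0.28; adjusted p = 0.0241, and 0.0842 with the block), beside Cd4 (-2.67 ± 0.94) and Foxp3 (-1.93 ± 0.68), which did not pass (adjusted p = 0.208 for either). Type I interferon response genes were lower for 2 of 18 (3 adjusted over the list alone, and 0 with the block, camera adjusted p = 0.00028, and adjusted p = 0.183 with an estimated correlation), namely Usp18 (-0.98 ± 0.19; adjusted p = 0.0346, and 0.0547 with the block) and Oas1a (-0.94 ± 0.20; adjusted p = 0.0485, and 0.132 with the block).

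Tissue residency genes were lower in TINT for 1 of 13 (1 higher and 4 lower adjusted over the list alone, and 0 with the block, camera adjusted p = 0.00105, and adjusted p = 0.0626 with an estimated correlation). The gene called was the integrin gene Itgae, at 129.8 ± 22.2 against 516.9 ± 238 (-1.86 ± 0.35; adjusted p = 0.0316, and 0.105 with the block). Inhibitory receptors and exhaustion regulators were lower for 1 of 14 (1 higher and 5 lower adjusted over the list alone, and 0 with the block, camera adjusted p = 0.00135, and adjusted p = 0.379 with an estimated correlation). Cd160 was called (-0.63 ± 0.13; adjusted p = 0.0426, and 0.127 with the block), and Cd200 was not (-2.23 ± 0.50; adjusted p = 0.0605, and 0.0103 without TMEM 4). Cytokine receptors were lower for 1 of 17 (5 adjusted over the list alone, and 0 with the block, camera adjusted p = 0.000305, and adjusted p = 0.183 with an estimated correlation), the gene called being Il7r. Calls of Cd160, Usp18, Oas1a, Itgae and Tnfrsf4 did not hold without TMEM 1 (adjusted p 0.0807 to 0.155), TMEM 2 (0.116 to 0.195), TINT 3 (0.101 to 0.128) or TINT 4 (0.0555 to 0.106), and those of all but Tnfrsf4 did not hold without TINT 1 (0.052 to 0.113) or TEFF 3 (0.058 to 0.0715). Cd160, Usp18 and Oas1a lost theirs without TMEM 4 (0.0642 to 0.0864), and Oas1a without TEFF 1, 2 or 4 (0.0511 to 0.0667). NK-type receptors passed with Klrg1, on which cells were sorted, as the gene called (1 of 13, and 1 adjusted over the list alone, camera adjusted p = 0.0333, and adjusted p = 0.333 with an estimated correlation), and not without TMEM 1 (0.0813), TMEM 4 (0.0946) or TINT 4 (0.189), nor after quantile normalisation (0.0335 to 0.0617 over 28 lists).

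Marker lists in TINT against TMEM rested on few libraries. Erythroid markers had a median of 1.87 (0 of 7 called, and 0 adjusted over the list alone, camera adjusted p = 0.00844, and adjusted p = 0.379 with an estimated correlation), and adjusted p of 0.155 without TMEM 2 and 0.0515 without TINT 4. Hba-a1 was at 2308 ± 1030 against 1199 ± 1670 (2.03 ± 0.84; adjusted p = 0.296, and 0.00778 without TMEM 4). NK cell markers had a median of 0.57 (0 of 7 called, and 3 adjusted over the list alone, camera adjusted p = 0.0333, and adjusted p = 0.405 with an estimated correlation), and adjusted p of 0.206 without TMEM 4 and 0.245 without TINT 4. With the replicate block, B cell (0.0719 to 0.0248), neutrophil (0.447 to 0.0212), platelet (0.433 to 0.035) and gamma delta T cell markers (0.212 to 0.0449) came under 0.05, with 0 genes of these lists called in either fit. The adjusted p of antigen-presenting myeloid cell markers was 0.414. T cell identity genes came under 0.05 after quantile normalisation (0.41 to 0.00953 over 28 lists, 1 of 14 called lower). Without TMEM 1, TMEM 2 and TINT 4, which leaves 1 TMEM library, Hba-a1 was at -0.866 in TINT against TMEM. No call in this comparison is read from that fit.

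The largest rises in TINT over TMEM besides Klrg1 were P3h4 (176.1 ± 20.2 against 18.32 ± 8.29; 3.29 ± 0.40; adjusted p = 0.00793), Gprc5a (3.08 ± 0.43; adjusted p = 0.0119, and 0.0621 without TMEM 2), Fpr1 (3.51 ± 0.74), Pparg (3.43 ± 0.69) and Dagla (3.16 ± 0.63). Klrg1 and P3h4 kept their calls without any single library. Fpr1, Pparg and Dagla had adjusted p of 0.0495, 0.0424 and 0.0417, and 0.088, 0.0632 and 0.0662 with the replicate block. They lost their calls without TMEM 2, TMEM 4, TINT 1, TINT 3, TINT 4 or TEFF 3 (adjusted p 0.0524 to 0.16), Fpr1 and Pparg also without TMEM 1 (0.157 and 0.107) or TEFF 4 (0.0652 and 0.0572), and Fpr1 without TEFF 1 (0.0587) or TEFF 2 (0.0576). The largest falls were Atp1b1 (-3.74 ± 0.72), Gpr55 (-3.72 ± 0.61), Xkrx (-3.62 ± 0.68), the gut-homing receptor gene Ccr9 (-3.38 ± 0.58), Izumo1r (-3.05 ± 0.58) and St6gal1 (-2.67 ± 0.53). Their adjusted p were 0.0216 to 0.0422, and 0.0547 to 0.133 with the block. None held without TMEM 1, TMEM 2, TINT 1 or TINT 3 (0.0556 to 0.173). Gpr55, Izumo1r and St6gal1 did not hold without TINT 4 (0.0524 to 0.0846), Atp1b1, Xkrx, Izumo1r and St6gal1 without TEFF 3 (0.0525 to 0.0615), and Xkrx without TMEM 4 (0.0504). Fpr1 averaged 226.2 ± 269 and Pparg 77.24 ± 71.5 in TINT. Without TINT 4, Fpr1 was at 2.544, Pparg at 2.701 and Dagla at 3.568. Without TMEM 1, TMEM 2 and TINT 4, 1 TMEM library is left. Ccr9 was then at -2.174, Izumo1r at -1.443, Gpr55 at -2.54, Atp1b1 at -2.987, St6gal1 at -2.214 and Xkrx at -3.71. Whether these transcripts came from T cells or other cells was not tested.

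Against the midpoint of TMEM and TEFF, TINT cells were higher in cell division genes, though neither list of these passed with an estimated correlation (camera adjusted p = 0.474). TMEM was itself above TEFF for both lists (medians 2.29 for G2/M and 1.71 for S phase). A level close to that of TMEM therefore already lies above the midpoint. Against TMEM, 0 of 28 genes of either list were called and the medians were 0.57 and 0.48. Both lists passed there at the preset correlation but not with an estimated one or by fry. Mki67 was 1.70 ± 0.27 above the midpoint on the log2 scale (adjusted p = 0.00297). All 28 G2/M genes (28 adjusted over the list alone, median 1.74, camera adjusted p = 5.53e-25) and 26 of 28 S phase genes (27 adjusted over the list alone, median 1.31, camera adjusted p = 1.79e-22) were above it. By fry both lists passed against the midpoint (adjusted p = 0.00728 for either). Ccna2 was 2.23 ± 0.23 above, Clspn 2.15 ± 0.25, E2f8 2.10 ± 0.25, Cdca3 2.06 ± 0.24, Ube2c 2.06 ± 0.25, Hmmr 1.91 ± 0.23, Uhrf1 1.77 ± 0.21 and Gmnn 1.68 ± 0.18. No call against the midpoint is read from the fit without TMEM 1, TMEM 2 and TINT 4, which leaves 1 TMEM library. Tcf7 was below the midpoint (-0.70 ± 0.15; adjusted p = 0.0151), but not called without TINT 1 (0.052) or TINT 3 (0.0855), and Gzmb was not separated from it (0.26 ± 0.15; adjusted p = 0.318). Klrg1 was above it (1.73 ± 0.16; adjusted p = 0.000309), as was Cxcr3 (0.91 ± 0.18; adjusted p = 0.00948, 0.0628 without TINT 3 and 0.0505 without TINT 4). TINT was sorted as positive for both proteins and TMEM and TEFF each for only 1, so these values check the labels and are no finding.

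In all, 999 genes were above the midpoint and 443 below. Such a call does not by itself set TINT apart from TMEM, since a gene at the TMEM level departs from the midpoint where TMEM and TEFF differ. The share of called genes above the midpoint was 69.3%, and 55.7% after quantile normalisation (922 above and 734 below). Oxidative phosphorylation genes were above for 9 of 27 (13 adjusted over the list alone, and 4 with the replicate block, camera adjusted p = 2.05e-06, and adjusted p = 0.53 with an estimated correlation) and glycolysis enzymes for 6 of 14 (7 adjusted over the list alone, camera adjusted p = 0.00264, and adjusted p = 0.53 with an estimated correlation). Members included Gapdh at 1.05 ± 0.14 and Tpi1 at 0.86 ± 0.12. Cholesterol synthesis genes were above for 3 of 15 (3 adjusted over the list alone, and 1 with the block or after quantile normalisation, camera adjusted p = 0.00112, and adjusted p = 0.53 with an estimated correlation). NK-type receptors were above for 1 of 13 and below for 2 (1 and 7 adjusted over the list alone, and 5 below with the block, camera adjusted p = 0.0308, and adjusted p = 0.511 with an estimated correlation). Members included Klrb1c at -1.34 ± 0.16. T cell identity genes were below for 1 of 14 (1 adjusted over the list alone, camera adjusted p = 0.0308, and adjusted p = 0.538 with an estimated correlation), which was Cd3e (-0.81 ± 0.12), and for 5 after quantile normalisation (0.0272 to 0.00136 over 28 lists). Cytokine receptors were below for 2 of 17 (1 above and 3 below adjusted over the list alone, and 1 with the block, camera adjusted p = 0.0433, and adjusted p = 0.53 with an estimated correlation). By fry, glycolysis enzymes passed against the midpoint (adjusted p = 0.0274), and oxidative phosphorylation and cholesterol synthesis genes did not (0.0518 for either). In TINT against TMEM, 0 of 14 glycolysis enzymes (camera adjusted p = 0.158) and 0 of 15 cholesterol synthesis genes (0.191) were called. Of 27 oxidative phosphorylation genes 0 were called there, and that list passed at the preset correlation but not with an estimated one.

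Of 9 lists of markers of other cells, 2 were also above the midpoint at the preset correlation. Those of antigen-presenting myeloid cells were above for 4 of 16 (4 above and 1 below adjusted over the list alone, camera adjusted p = 0.0308, and adjusted p = 0.588 with an estimated correlation). Members included Itgax at 1.39 ± 0.19, Cd14 at 3.38 ± 0.66 and Csf1r and Adgre1 at 3.54 ± 0.70. Itgax was even across TINT libraries (3229 to 4006), while Csf1r was at 633, 700 and 9372 in TINT 1, TINT 3 and TINT 4. Erythroid markers were above for 2 of 7 (4 adjusted over the list alone, camera adjusted p = 0.00649, and adjusted p = 0.53 with an estimated correlation), and for 0 without TINT 3 or TINT 4. Hbb-bs (2.58 ± 0.61; adjusted p = 0.022) had adjusted p of 0.081 and 0.102 without these. Hba-a1 (2.55 ± 0.71; adjusted p = 0.0443) lost its call without any single library other than TMEM 4 (0.0549 to 0.163). The largest departures upward were macrophage genes, Cd5l (4.71 ± 0.73), Mertk (4.61 ± 0.81), Mrc1 (4.46 ± 0.85) and the complement genes C1qc (4.33 ± 0.68) and C1qb (4.32 ± 0.68), and Fpr1 (4.31 ± 0.63). C1qb averaged 2862 ± 3740 in TINT, with 7183 in TINT 4. Without TINT 4 these departures were 3.118 (C1qc) to 3.661 (Cd5l). Without TMEM 1, TMEM 2 and TINT 4, which leaves 1 TMEM library, they were 2.903 (C1qc) to 3.659 (Mrc1), with Mertk at 2.994. The largest downward were Gatsl2 (-1.80 ± 0.41; adjusted p = 0.0178, 0.0915 without TINT 3 and 0.0571 without TINT 4), Peg13 (-1.67 ± 0.19), Evl, an actin-binding protein gene (12:108554720-108688516; -1.62 ± 0.11), Per3 (-1.55 ± 0.24), Dmrta1 (-1.53 ± 0.33; adjusted p = 0.0152, and 0.0877 without TINT 3) and Aqp9 (-1.52 ± 0.22). With the block, interferon response genes (0.147 to 0.0451) and neutrophil markers (0.167 to 0.00511) came under 0.05.

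Calls against the midpoint depended on single libraries. Without TINT 3, 444 genes were above and 113 below, without TINT 4 it was 515 and 204, and without TEFF 3 there were 276 below. With the level of markers of other cells as a covariate 586 were above and 213 below, with the ribosomal RNA level 581 and 143, and with array weights 1637 and 1011. Oxidative phosphorylation genes above were 0 without TINT 3 and 1 without TINT 4, glycolysis enzymes 2 without either, and cholesterol synthesis genes 0 without TMEM 1, TMEM 4, TINT 1, TINT 3, TINT 4 or TEFF 3. The NK-type list lost its call without TMEM 2 (0.0545), TINT 1 (0.0961) or TINT 3 (0.0534), the antigen-presenting list without TMEM 4 (0.245), TINT 1 (0.09) or TINT 4 (0.0839), the T cell identity list without TMEM 2 (0.0545), TMEM 4 (0.0687), TINT 1 (0.137), TINT 3 (0.0696) or TEFF 3 (0.0513), and the cytokine receptor list without TMEM 1 (0.0546), TMEM 4 (0.0687), TINT 1 (0.135), TINT 3 (0.0714) or TEFF 3 (0.084).

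Genes called above both other sorts in TINT numbered 24, where independent lists would share 12 and simulated unchanged groups 0.01, and 13 were below both (11.4 for independent lists and 0 simulated). Both comparisons share the TINT libraries, which independent lists ignore, and the simulated groups held no changed genes. Neither baseline therefore shows that 24 above or 13 below is more than expected. With the replicate block these were 7 and 5. The numbers above and below were 4 and 3 without TMEM 1, 2 and 0 without TMEM 2, 14 and 9 without TMEM 4, and 11 and 8 without TINT 1. They were 1 and 2 without TINT 3, 3 and 8 without TINT 4, and 9 and 4 without TEFF 3. Below both there were also 8 without TEFF 4.

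On the axis from TEFF to TMEM, TINT lay at 0.72 ± 0.10 (SD, n = 3, libraries 0.64 to 0.83), where 0 is the TEFF mean and 1 the TMEM mean. TMEM 4 lay at 0.831 and TINT 4 at 0.834, so libraries of these sorts overlapped on the axis. The axis held 4059 genes, 2268 higher and 1791 lower in TMEM. For 2464 of them (60.7%) the TINT mean lay between the other sorts, for 1492 it lay beyond TMEM and for 102 beyond TEFF. No test was made of this position. It was 0.606 without TMEM 1, TMEM 2 and TINT 4.

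Calls against TEFF were shared between TMEM and TINT to a large degree. Of genes higher in TMEM and genes higher in TINT, 1645 were in common, where independent lists would share 376 and simulated unchanged groups 0. Of genes lower, 1261 were in common against 236.3 for independent lists, and 5 genes went in opposite directions. Independent lists ignore the shared TEFF libraries, and the simulated groups held no changed genes, so neither is a full baseline. With the TEFF libraries split so that each comparison had its own, 984.7 (931 to 1103) and 635 (563 to 748) were shared on average. Across genes, which are not independent replicates, the fold changes of both comparisons correlated at 0.79 (0.43 simulated, 0.65 with split TEFF libraries). Their covariance was 0.82 against a simulated 0.09, a difference of 0.73.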

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

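The tests of antigen-presenting cell markers, the slope of ribosomal protein genes on markers of other cells, and the fits that leave out TMEM 1, TMEM 2 and TINT 4 or use a covariate, were chosen after the result was seen.

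Antigen-presenting myeloid cell markers were higher in TMEM and TINT than in TEFF, by medians of 2.71 and 2.52 on the log2 scale. Of the 16 genes measured, 0 were in another list and 14 averaged at least 10 in TEFF. Their median within-sort SD of 1.2 lay at percentile 100 of matched gene lists, whose median was 0.28 and 95th percentile 0.35. That test restates that TMEM 1, TMEM 2 and TINT 4 stood apart, and a spread does not show that the markers varied together. Siglech was at 4335 and 2193 in TMEM 1 and TMEM 2 and at 51 in TINT 4, while Csf1r was at 346, 268 and 9372. The list took 55.4 and 46.18 per 10000 normalised counts in TMEM 1 and TMEM 2 but 10.88 in TMEM 4. It took 50.75 in TINT 4 but 19 and 8.54 in TINT 1 and TINT 3. Such gaps argue against transcription shared by all T cells of a sort as the whole source. TEFF libraries held 3.42 to 5.33, less than any of these, so transcription by the CXCR3+ T cells stays open for part of the rise. RNA from other cells stays open as well. The sort gate required tetramer binding and took cells without B220 and CD4. How far it removed dendritic cells and macrophages was not measured, and their presence remains a hypothesis.

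Replication histone transcripts, a set chosen after its values were seen, were higher in TINT than in TEFF for 38 of 53 genes and lower for 1 (median 2.70). With the ribosomal RNA level as a covariate the median was 2.40. Only 12 of the 38 genes stayed past the threshold then, because the SE grew from 0.38 to 0.98 as the covariate ran with the sorts. For that reason this fit cannot separate more RNA without a poly(A) tail from a difference between the sorts, and that cause stays open. With the S phase level as a covariate the median was 2.43 and 0 of the 38 passed by limma (SE 1.45), so a larger share of cells in S phase stays open. Reads shared between histone copies were not tested.

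Cytoplasmic ribosomal protein genes, also a set chosen after its values were seen, were higher in TMEM than in TEFF for 72 of 83 genes (median 0.73). The camera adjusted p was 2.5e-20 at the preset correlation and 0.13 with an estimated one. After subtraction of a trend with transcript length and GC content, the median was 0.52, while random lists reached at most 0.21, which argues against that trend as the whole cause. Without TMEM 1, TMEM 2 and TINT 4 it was 0.89. That leaves 1 TMEM library and decides nothing alone. Counts of mixed cells add up, and within sorts the share of these genes changed by -0.05% of counts (95% CI -0.19 to 0.10) for each 10 per 10000 of antigen-presenting, B and plasma cell markers. The rises in TMEM and TINT would need 0.35 and 0.55, and the upper limit was 0.23 or less without any single library. This argues against cells with these markers as the whole source. With mean log2 levels in place of shares, the upper limit was 0.31 against 0.32 and 0.45 needed, and reached 0.43 without TINT 3 or TINT 4, so on that scale single libraries decided. With the ribosomal RNA level as a covariate the median was 0.30 and 1 of the 72 genes passed (SE 0.15 before and 0.24 after), so more ribosomal RNA in these libraries could account for it. That level ran with the sorts, and a biological difference in ribosome content was not tested apart from it.

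In TMEM against TEFF, fitted on these sorts alone, 1 of 35 splits (the real one) called as many as 4059 genes, and the highest other called 8. In TINT against TEFF 1 of 35 called as many as 3875, and the highest other called 3. Over all 35 splits the share is under 0.05 for both, but libraries are paired by mouse, so the splits are not all interchangeable and chance is not excluded. Of these, 8 splits of either set part all 3 pairs of the same mouse, too few alone for a share under 0.05. The highest other of those 8 called 0 and 1, and the splits that part fewer pairs reached 8 and 3. In TINT against TMEM the real split called 75 and the highest other 19, and 10 splits are too few for a share under 0.05. For TINT against the midpoint 3 of 100 regroupings called at least 1442, the real one included. The highest other called 3085 and the next 2859, and both put TEFF 1, TEFF 3 and TEFF 4 in the middle group, which points to the structure of the samples.

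Among 159 sets of 4 TEFF values, 8 had a library far from the others by Dixon's ratio on the log2 scale (critical value 0.829), where chance gives about 1 in 20. They were Socs3 (0.865, TEFF 4 at 3.14 against 14.8 to 18.5), Hba-a2 (0.845, TEFF 2 at 32.9 against 93.4 to 113), Xkrx (0.897, TEFF 4 at 31.4 against 6.94 to 8.18) and Izumo1r (0.897, TEFF 3 at 10.9 against 5.64 to 6.05). The others were Gzmk (0.858, TEFF 2 at 4050 against 3200 to 3310), Itgae (0.856, TEFF 1 at 122 against 179 to 191), Klrk1 (0.829, TEFF 1 at 15800 against 21100 to 22400) and the mitochondrial share (0.915, TEFF 4 at 2.45% against 1.58 to 1.64%).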

How the results depend on the processing

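Fits that leave out TMEM 1, TMEM 2 and TINT 4 or use a covariate were chosen after the data were seen. Over all settings, named genes kept direction and side of the threshold in 1451 values of TMEM against TEFF (89 lost the call and 4 reversed), 1566 of TINT against TEFF (86 lost, 10 gained, 5 reversed), 1367 of TINT against TMEM (255, 38 and 7) and 1174 of the midpoint comparison (138, 29 and 2). Position moved by less than its SD in 13 of 14 settings. Count tests on whole reads were not run, since whole reads were not recovered, and the midpoint comparison has no fit of only the sorts compared. At 19340584 or more normalised counts per library, genes under 10 counts were largely outside the tests.

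With no filter, 291 genes were below the midpoint and 6 below both sorts. Quantile normalisation gave 734 and 29. With only the sorts compared in the fit, 28 genes were higher and 47 lower in TINT than in TMEM. With no variance trend these were 29 and 40, with 9 above both sorts and 4 below both. Array weights gave 365 and 408 in TINT against TMEM, 1637 above and 1011 below the midpoint, 167 above both and 78 below both, and Fcer1g at -0.008 in TINT against TMEM. The fixed replicate block gave 35 and 26 in TINT against TMEM, and 7 and 5 outside both. For these the cause was not tested.

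Leaving out 1 library gave, for genes lower, 1190 to 2059 in TMEM against TEFF (1190 without TMEM 1, 1209 without TMEM 2) and 1250 to 2091 in TINT against TEFF (1250 without TINT 3). In TINT against TMEM it gave 7 to 94 higher and 2 to 102 lower, with 23 and 19 without TMEM 1, 7 and 2 without TMEM 2, 33 and 25 without TINT 1, 14 and 10 without TINT 3, 13 and 33 without TINT 4, and 37 and 42 without TEFF 3. Midpoint counts were 444 to 1091 above and 113 to 626 below, with 444 and 113 without TINT 3, 515 and 204 without TINT 4, and 276 below without TEFF 3. Genes above both were 1 to 32 and below both 0 to 19. Fcer1g in TINT against TMEM ranged from -0.14 to 1.487, negative without TMEM 4 or TINT 4. The cause of these differences was not tested.

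Without TMEM 1, TMEM 2 and TINT 4, where the lone TMEM library is assumed to vary like the other groups, 473 and 296 genes were higher and lower in TMEM against TEFF, 1504 and 1158 in TINT against TEFF, 1 and 1 in TINT against TMEM, and 408 and 137 against the midpoint. Above both were 0 (24 with all libraries) and below both 1, and the position was 0.606. In TINT against TMEM the haemoglobin genes reversed, Hba-a1 to -0.866, Hba-a2 to -0.835, Hbb-bs to -0.889 and Hbb-bt to -0.73, as did the erythroid list (adjusted p = 0.3). List calls lost were immediate early genes (adjusted p = 0.173), glycolysis (0.104) and cholesterol synthesis (0.363) in TMEM against TEFF, B cell markers (0.229) in TINT against TEFF, and cytotoxic molecules (0.0831), inhibitory receptors (0.191) and NK-type receptors (0.112) in TINT against TMEM. Tcf7 (0.222), Cx3cr1 (0.273) and P3h4 (0.217) lost their calls in TINT against TMEM. List calls gained included erythroid (0.00139) and NK cell markers (0.0284) in TMEM against TEFF, neutrophil markers in TINT against TEFF (0.0277), TMEM (0.000843) and the midpoint (0.00212), and, in TINT against TMEM, B cell markers (0.000358), cholesterol synthesis (0.00102), chemokine receptors (0.0111), T cell identity genes (0.0351) and glycolysis (0.0499). Interferon response (0.0278) and tissue residency genes (0.0298) were gained against the midpoint.

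Covariates ran with the sorts and left 1 fewer residual degree of freedom. With the level of markers of other cells, 107 and 75 genes were called in TMEM against TEFF, 532 and 239 in TINT against TEFF, 58 lower in TINT against TMEM, 586 and 213 against the midpoint, 3 above both and 3 below both. In TMEM against TEFF Ighm (-0.095), Igkc (-0.167), Cd79b (-0.351) and H2-Eb1 (-0.053) reversed, with the B cell (adjusted p = 0.587) and antigen-presenting (0.872) lists. In TINT against TEFF Igkc (-0.648), Ighm (-1.172) and the B cell list (0.327) reversed. Genes of the antigen-presenting, B and plasma cell lists make up that level. Reversals and lost calls among them were therefore largely fixed in advance and decide nothing. Other list calls lost were interferon response (0.501), immediate early (0.183) and cholesterol synthesis (0.237) in TMEM against TEFF, inhibitory receptors (0.144), antigen-presenting (0.453) and erythroid markers (0.0566) in TINT against TEFF, and cytokine receptors (0.0629) and antigen-presenting markers (0.23) against the midpoint. List calls gained were NK cell markers in TMEM (7.66e-05) and TINT against TEFF (0.0296), and interferon response and CD4 and regulatory T cell markers against the midpoint (0.0343 for either). With the ribosomal RNA level the counts were 827 and 451, 688 and 267, 158 higher in TINT against TMEM, 581 and 143 against the midpoint, and 78 above both. Tcf7 (0.521), Gzmb (0.349) and Alas2 (-0.32) reversed in TINT against TEFF, and Il2rg (0.162) and Lck (0.047) against the midpoint. List calls lost were interferon response (0.0887) and B cell markers (0.127) in TMEM against TEFF, and B cell (0.509), erythroid (0.521) and T cell identity genes (0.274) in TINT against TEFF. In TINT against TMEM they were NK-type receptors (0.0866), erythroid (0.0645) and NK cell markers (0.0661), and against the midpoint NK-type (0.17) and cytokine receptors (0.17), erythroid (0.267) and T cell identity genes (0.267). Calls gained were oxidative phosphorylation in TMEM against TEFF (0.000363), neutrophil markers in TMEM against TEFF (0.0103) and in TINT against TEFF (0.00371) and the midpoint (0.00631), and cholesterol synthesis in TINT against TMEM (0.00633).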

Other observations

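Some T cell receptor V segments took large shares in several sorts of 1 mouse, a feature chosen after its values were seen. In mouse 1, Trbv26 took 30% of Trbv counts in TMEM, 55% in TINT and 32.1% in TEFF, against 0.3 to 3.2% in the libraries of the other mice. Trav16n took 38.8, 62 and 33.2% of Trav counts there, but also 28.6% in TMEM 4 and 24.9% in TINT 4. In mouse 3, Trbv1 took 85.8% in TINT and 87.1% in TEFF, against 12.1 to 75% in the other libraries. In mouse 4, Trbv13-1 took 52.5% in TMEM, 43% in TINT and 17.8% in TEFF, against 17.3% in TEFF 2. These are shares of counts in 1 library each, and no test was made of a difference between sorts.

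The genes above both other sorts in TINT, named here after their values were seen, included the metallothionein genes Mt1 (493.1 ± 105 in TINT, 179.4 ± 23.8 in TMEM and 214.2 ± 46.8 in TEFF), Mt2 (127.1 ± 40, 38.64 ± 7.28 and 53.09 ± 14.3) and Mt3 (348.9 ± 89.3, 89.05 ± 7.81 and 105.3 ± 20; SD, n = 3, 3 and 4). They also included the tubulin genes Tubb3, Tuba1a and Tuba1c and the cell cycle transcription factor gene Mybl2 (634.4 ± 101, 243.9 ± 32.1 and 78.04 ± 29.4). Those below both included Evl (633.5 ± 49.3, 1273 ± 137 and 3009 ± 213), Pik3ip1 (1070 ± 193, 1861 ± 234 and 2302 ± 78.8) and Parp8 (229.1 ± 22.2, 507.9 ± 51.2 and 526.4 ± 38.5). Above both sorts there were 7 genes with the replicate block, 1 without TINT 3, 2 without TMEM 2 and 3 without TINT 4, so most of the 7 named did not hold without these libraries. Below both there were 5 with the block, 2 without TINT 3 and 0 without TMEM 2. Reads shared between metallothionein or tubulin copies were not examined.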
